A study of Mus musculus with 6 samples.

How the data were processed

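RNA was measured in 6 libraries of BMP-2-treated primary chondrocytes, 3 from control and 3 from Uhrf1 cKO mice. Per the labels' protocols, total RNA had an integrity number over 8 and libraries were made with a stranded mRNA kit. Per the series text, libraries were sequenced on an Illumina MiSeq, reads were mapped to mm10 with TopHat, and Cufflinks was used for the analysis. Tool versions, the annotation, the strand setting and the scaling between libraries are not given in the sources used here. The authors deposited 1 gene table of 23351 genes with an FPKM value per library and per group mean, per the file headers. It also holds, per the file headers, the authors' log2 fold change, a test statistic (a score), a p-value, a q-value and a test status. The recomputed and deposited control means differed by at most 0.00667 FPKM. Symbols of 27 genes had turned into dates and were not used as names, 101 entries held several symbols, and 1 line of the table was empty and is not reported here. Genome coordinates are from the table, counted from 1.

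FPKM are not counts, so no count test was used. Low values come in steps that depend on gene length, which gave relative but not absolute depth, and whole reads could not be recovered. An exact 0 may be a failed estimate. None of 20 housekeeping genes checked was at 0 in any library. The median coefficient of variation between controls was 20.6% for genes of 1 to 5 FPKM and 8.05% for genes over 100 FPKM, so values of low genes are less precise.

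Genes with at least 1 FPKM in 2 or more libraries (11911) were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust options) on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fitted differences are on the log2(FPKM + 1) scale, which understates the change of low genes. Folds in the text are ratios of group mean FPKM, and none is given against a group mean under 1 FPKM. Data were simulated for 11911 genes with independent normal noise, each gene's spread drawn around the trend of these libraries with expression level. The test recovered 40.3% of 67 genes shifted by 0.5 on the log2 scale, 94.0% of 67 shifted by 1 and 100% of 66 shifted by 2. There were 11 false calls among 167. Far fewer genes were shifted than the 2116 called in the data, so these shares need not hold there.

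Before the data were examined, 24 gene lists, the rule for named genes, the tests and most alternatives were fixed. Lists of at least 5 tested members (21) were tested by a two-sided Fisher's exact test of called against other genes, by the place of the median log2 ratio among 10000 random lists matched on expression in 10 bins, and by limma's camera with a preset correlation of 0.01 and with an estimated one, each adjusted over the lists. Fisher's test called 10 lists, the random lists 14 and camera 11 at the preset correlation and 1 with estimated correlations. Genes of a list are not independent, so percentiles describe these libraries. The 24 lists are those named in the report. Another 4 lists, antigen presentation, chaperones of the endoplasmic reticulum, cholesterol synthesis and smooth muscle genes, were chosen after seeing the data.

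Named genes are Uhrf1, Hspb1 (from background knowledge of the published study), the 12 largest rises and 12 largest falls in the ratio of means among called genes with at least 5 FPKM in the higher group and a value above 0 in the other, up to 4 genes listed at 0 in a group, and up to 4 called members per list by the size of the ratio, or the 2 most highly expressed where fewer than 2 were called. Short RNAs, histone genes, unnamed genes and entries with several symbols were left out of the largest changes. Col2a1, Acan, Sox9, Runx2, Ifit2 and Cd14 were named outside this rule, after their values were seen. Alternatives were another threshold, a minimum difference, other expression filters, 2 scalings, other pseudocounts, a block for replicate number and leaving out each library. The authors' deposited test, a covariate for Y-linked transcript, leaving out the sex chromosomes and testing all genes above 0 in any library were added after seeing the data. Genes that overlap or belong to multi-copy families are uncertain, since how reads were shared among them is not given in the sources used here.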

Results

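The transcriptomes of mouse primary chondrocytes with and without Uhrf1 were compared by RNA sequencing. Uhrf1 encodes a protein that binds hemimethylated DNA and recruits the maintenance methyltransferase Dnmt1 after replication. The cells were digested from knee cartilage of C57BL/6 mice on postnatal day 3, grown to confluence and treated with 100 ng/ml recombinant BMP-2, a growth factor that drives chondrocyte differentiation, for 24 hours. There were 3 libraries from control and 3 from Uhrf1 conditional knockout (cKO) mice. Each gene had 1 value per library in FPKM, a fragment count scaled to transcript length and library size. Between 11233 and 11635 genes reached 1 FPKM in each library. Depth was unknown in absolute terms. The smallest value steps of low genes gave relative depths of 0.864 to 1.01, with Control 1 set to 1, so depth was similar in both groups.

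Replicates lay close together. Pearson's r across 11911 genes, which are not independent replicates, was 0.981 to 0.984 within control, 0.983 to 0.986 within cKO and 0.946 to 0.956 between the groups. The first principal component held 63.8% of the variance and separated the genotypes. The labels do not say that the libraries came from separate animals or cultures, so p-values measure only the spread between these samples. That spread may be partly technical. The label prefix differs between all control and all cKO libraries, and whatever it stands for cannot be told apart from genotype. Y-linked transcripts were present in Control 1, Control 3 and cKO 1. Ddx3y, for example, stood at 31.6, 24.3 and 22.2 FPKM there and at 0 in the other libraries. Each group thus holds libraries that cannot be technical replicates of 1 sample, while libraries alike in these transcripts may be. Xist, the RNA of the inactive X chromosome, stood at 82.4 FPKM in Control 2, 77.9 in cKO 2 and 96.3 in cKO 3.

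The first question was whether the targeted gene was reduced. Uhrf1 (chromosome 17, 56303337 to 56323486, mm10; a protein-coding gene on the plus strand) stood at 27.2 ± 3.97 FPKM (SD, n = 3) in control and 3.04 ± 0.273 (SD, n = 3) in cKO cells, 8.96-fold lower. The values were 28.2, 22.9 and 30.6 in the controls and 3.22, 3.17 and 2.73 in the cKO libraries. The difference on the log2(FPKM + 1) scale was -2.80 with a standard error of 0.132 (limma, adjusted p = 1.7e-06). A gene-level value also counts transcript outside a deleted part, so the remaining 3.04 FPKM does not measure intact mRNA.

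**Figure D1:**
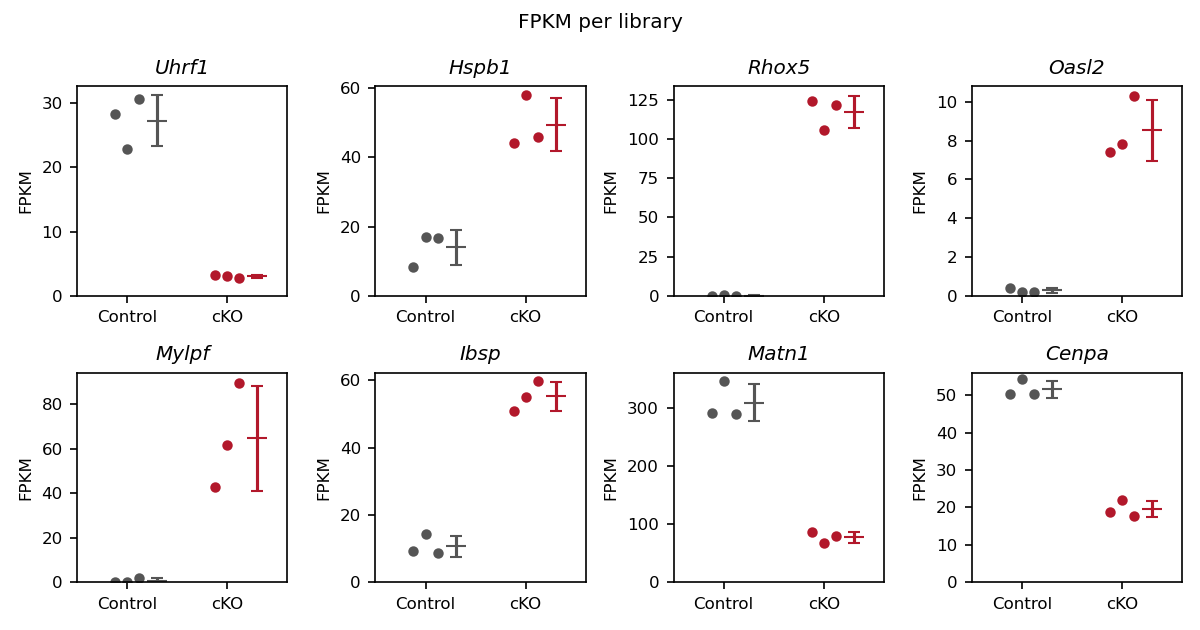
FPKM of 8 genes in each library, with control in grey and Uhrf1 cKO in red. Points are single libraries, and the bar beside them is the mean with its SD (n = 3). Uhrf1, Matn1 and Cenpa lie lower in all 3 cKO libraries than in any control, and Hspb1, Rhox5, Oasl2, Mylpf and Ibsp lie higher.

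The second question was which other genes differed. Many did, and the large changes were mostly rises. The genes with the highest ratio of cKO to control mean included Rhox5, a homeobox gene of the X-linked reproductive cluster (chromosome X, 37754608 to 37808878), at 0, 0.540 and 0 FPKM in the controls and 117 ± 10.05 (SD, n = 3) in cKO cells. Nxf3, an X-linked relative of the mRNA export factors, rose from at most 0.119 FPKM in any control to 12.4 ± 1.27. The interferon-inducible gene Trim30a reached 5.36 ± 1.04 FPKM, Mst1 17.5 ± 2.64, the inflammasome protease gene Casp1 5.36 ± 0.801 and the Fc receptor gamma chain gene Fcer1g 15.8 ± 3.77, all from control means under 0.3 FPKM. The others of the 12 were Mylpf and Myl1, which encode skeletal muscle myosin light chains, AI662270, Olfr875, Psg23 and Xlr. Of the 12, the authors' deposited test, added after the data were seen, called only Xlr (q = 0.0154). The rest had q = 0.0600 to 0.457 in that test. Cox7b2, Slc47a1, Rhox2d and Ankrd1 were listed at 0 in all 3 controls. They stood at 33.4 ± 5.70, 19.2 ± 2.08, 19.03 ± 3.998 and 18.5 ± 0.781 FPKM in cKO cells. The authors' test called each of them (q = 0.000520).

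The falls were smaller. The largest ratio of means was that of Akr1b7, an aldo-keto reductase gene, which fell from 5.07 ± 1.15 to 0.420 ± 0.466 FPKM. Uhrf1 came next. The authors' deposited test called Uhrf1 (q = 0.000520) but not Akr1b7 (q = 0.141). The protease inhibitor gene A2m fell 6.71-fold (43.6 ± 5.70 to 6.50 ± 1.91 FPKM), the secreted Wnt modulator Sfrp2 6.26-fold and the cartilage matrix gene Matn1 3.99-fold (309 ± 32.6 to 77.4 ± 9.69). Tbx4, a transcription factor of hindlimb patterning, fell 3.95-fold. Mdk, U90926, Spink5 and Mttp fell 4.37-, 4.36-, 3.78- and 3.41-fold. Il1rn, the interleukin-1 receptor antagonist gene, fell 4.12-fold, but its call was lost without Control 3 (adjusted p = 0.0688). Gng13 fell 3.90-fold, and its call was lost without Control 1, 2 or 3 or cKO 1 or 2 (adjusted p = 0.0535 to 0.102).

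Of 11911 genes tested with limma on log2(FPKM + 1), 1168 were higher and 948 lower in cKO at an adjusted p under 0.05. A log2 difference of at least 1 was reached by 431 of the higher and 75 of the lower genes, and 80 of the higher genes were listed at 0 in all controls. Scaling the libraries to a common upper quartile gave 1392 higher and 681 lower genes, so the balance of the 2 directions depends on scaling. Without cKO 3 the numbers were 775 and 502, and the lower genes numbered 598 without cKO 1 and 629 without cKO 2.

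**Figure D2:**
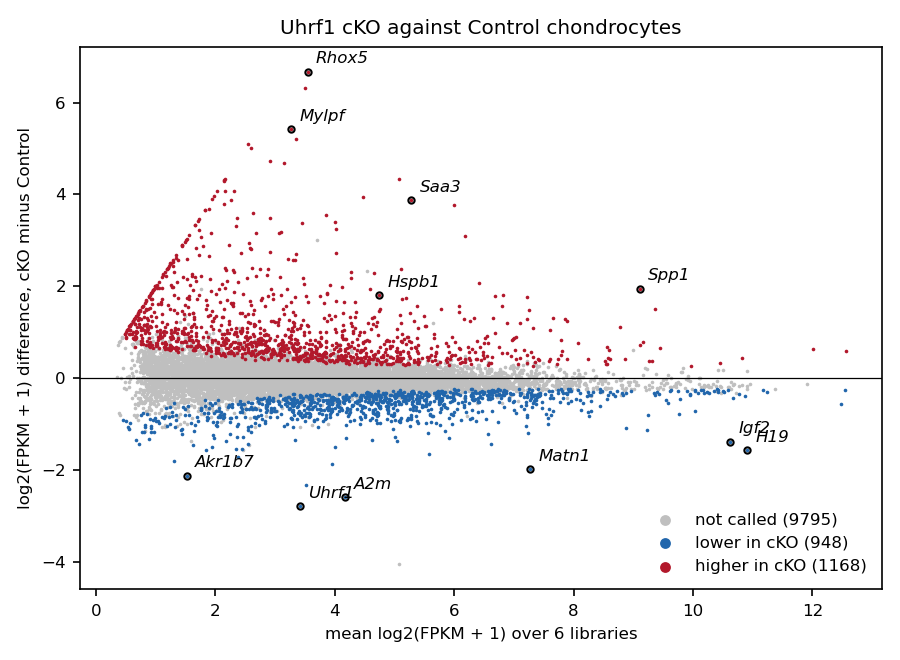
Difference between group means on the log2(FPKM + 1) scale (cKO minus control) against the mean log2(FPKM + 1) over the 6 libraries, 1 point per gene. The 1168 genes called higher are red, the 948 called lower blue and the others grey, and the differences of at least 1 are mostly rises (431 against 75).

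The cartilage identity of the cells was examined next. Of 24 tested genes of cartilage matrix and chondrocyte identity, 13 fell and 1 rose, with 14 lower and 2 higher adjusted over the list alone. Besides Matn1, the cytokine-like gene Cytl1 fell 2.99-fold, the type XI collagen gene Col11a2 2.38-fold (235 ± 70.9 to 98.7 ± 12.6 FPKM) and Matn3 2.37-fold (71.3 ± 11.8 to 30.1 ± 1.48). Named outside the fixed rule after their values were seen, Col2a1 and Acan, which encode the main collagen and proteoglycan of cartilage, fell 1.51- and 1.75-fold. Sox9, the transcription factor of chondrocyte fate, was 37.9 ± 3.82 FPKM in control and 33.2 ± 2.84 in cKO (adjusted p = 0.268). The called members exceeded those of other genes (Fisher's exact test, adjusted p = 2.95e-05; adjusted p = 0.236 with an estimated correlation in camera). These falls stand beside rises of all 14 tested skeletal muscle markers and of 8 of 11 contractile genes, a list chosen after the data were seen.

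Of 16 tested genes of the hypertrophic, mineralising stage, 7 rose, 1 fell and 8 were not called, with 8 and 2 adjusted over the list alone. Ibsp, which encodes bone sialoprotein, rose 5.14-fold (10.7 ± 3.07 to 55.2 ± 4.35 FPKM), Spp1 (osteopontin) 3.73-fold, the collagenase Mmp13 3.42-fold (79.8 ± 7.89 to 273 ± 22.6) and the alkaline phosphatase Alpl 2.85-fold. Runx2, the regulator of hypertrophy, stood at 7.68 ± 0.920 FPKM in control and 8.40 ± 1.42 in cKO (adjusted p = 0.661). The list was called by Fisher's exact test (adjusted p = 0.00682; adjusted p = 0.136 with an estimated correlation). Of 10 osteoblast genes, Postn, Tnfrsf11b, Omd and Sp7 rose 2.60-, 2.38-, 2.20- and 1.84-fold and none fell, and 6 rose adjusted over the list alone. That list was not called by Fisher's exact test (adjusted p = 0.137), while the random lists and camera at the preset correlation did (adjusted p = 0.00105 and 0.00347; adjusted p = 0.136 with an estimated correlation). It was called by Fisher's exact test without Control 3, cKO 1 or cKO 3 (adjusted p = 0.0240, 0.0430 and 0.0284), and with all libraries at a threshold of 0.01, a log2 difference of at least 1, at least 5 FPKM or upper-quartile scaling (adjusted p = 0.0157, 0.0192, 0.0253 and 0.0353). The genes called by the authors' deposited test, added after the data were seen, also gave a call (adjusted p = 0.00503). Sp7 is also in the hypertrophic list.

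Superficial-zone and synovial fibroblast genes went both ways, with 6 of 16 higher and 3 lower, and 6 and 7 adjusted over the list alone. Postn rose, Gdf5, a joint-forming growth factor, rose 1.90-fold and the fibrillar collagen gene Col5a2 1.64-fold (433 ± 37.9 to 708 ± 38.5 FPKM). Cd34 fell 1.61-fold, a call held only without Control 2 (adjusted p = 0.05004 to 0.0840 without any other single library). Fisher's exact test called the list (adjusted p = 0.00139), but the call was lost without cKO 1 (adjusted p = 0.0579) or cKO 2 (adjusted p = 0.0765), at a threshold of 0.01 (adjusted p = 0.0750) and at a log2 difference of at least 1 (adjusted p = 0.701), and was adjusted p = 0.943 with an estimated correlation.

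**Figure D3:**
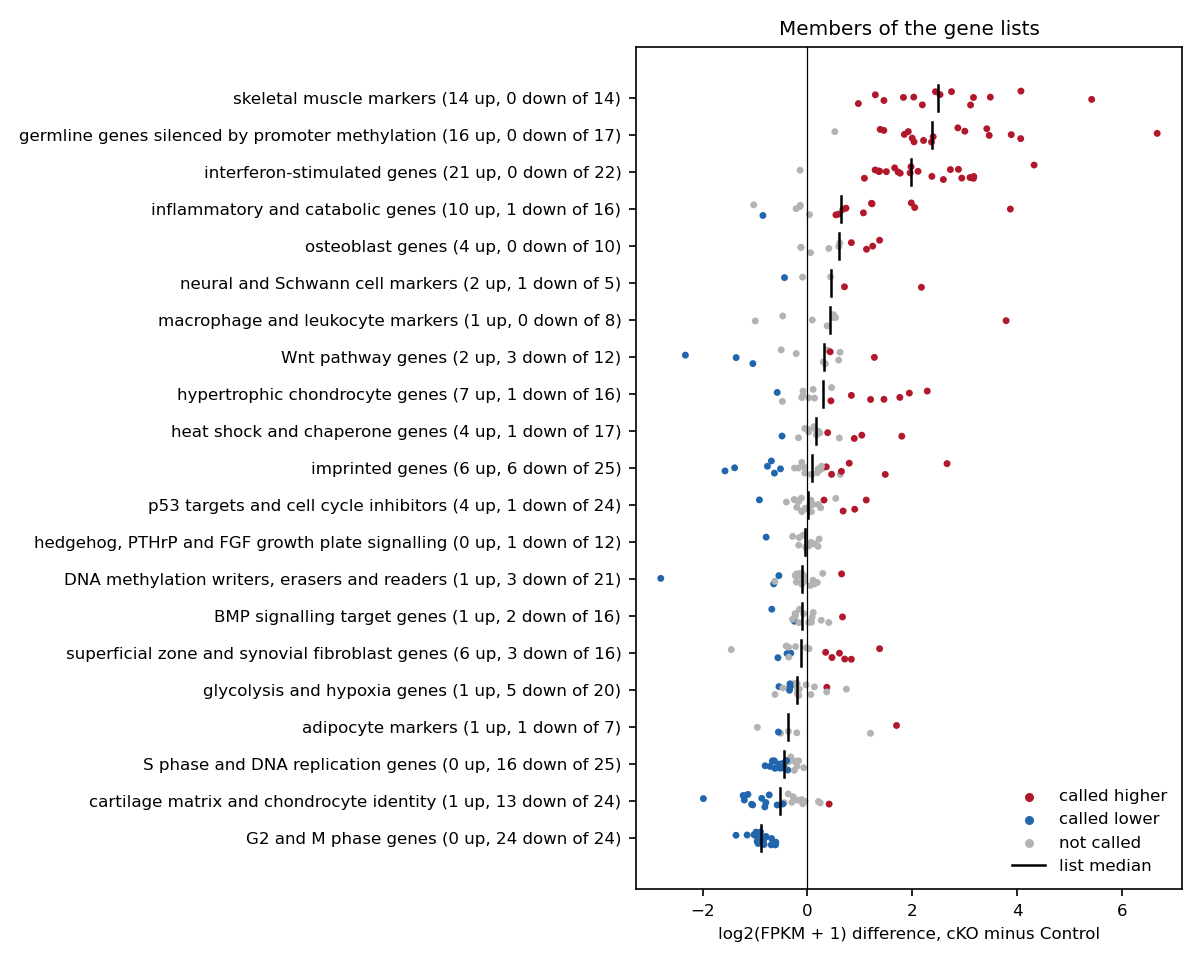
Difference on the log2(FPKM + 1) scale (cKO minus control) for each tested member of the 21 lists with at least 5 tested genes. Points are genes, coloured by call, and the bar is the list median. All 24 tested genes of G2 and M phase lie below 0, and all 14 skeletal muscle markers lie above 0.

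All 24 tested G2 and M phase genes were lower in cKO, adjusted over all genes and over the list alone. Cenpa, the centromeric histone, fell 2.64-fold (51.6 ± 2.26 to 19.5 ± 2.18 FPKM), the anaphase activator Cdc20 2.25-fold, cyclin B1 (Ccnb1) 2.05-fold (76.9 ± 7.11 to 37.6 ± 5.56) and the mitotic kinesin Kif20a 2.001-fold (58.7 ± 5.88 to 29.3 ± 4.74). Of 25 S phase and replication genes, 16 fell and none rose, with 19 lower adjusted over the list alone. Rrm2, a ribonucleotide reductase subunit, fell 1.75-fold, Gins2 1.62-fold and Mcm5 1.56-fold. Rfc4 fell 1.66-fold, and its call was lost without Control 1, Control 3, cKO 1 or cKO 3 (adjusted p = 0.0733 to 0.135). Fisher's exact test gave adjusted p = 1.84e-17 for G2 and M phase and 1.58e-06 for S phase, with adjusted p = 0.202 and 0.216 at an estimated correlation. The number of S phase genes called was 10 without Control 3, cKO 1 or cKO 3, and 12 after upper-quartile scaling. Most of these falls were small: with a log2 difference of at least 1 required, 3 of the 24 and 0 of the 25 genes were called and neither list was (adjusted p = 0.167 and 0.772).

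Among 24 p53 targets and cell-cycle inhibitors, 4 rose and 1 fell, also adjusted over the list alone, and the list was not called (Fisher's exact test, adjusted p = 0.743). Trp53inp1 rose 2.35-fold and Cdkn2a, the locus of p16 and p19, 2.17-fold (3.40 ± 0.152 to 7.36 ± 1.87 FPKM), while the inhibitor Cdkn2c fell 1.90-fold. Pmaip1 rose 1.95-fold, a call lost without Control 2, Control 3, cKO 2 or cKO 3 (adjusted p = 0.0730 to 0.105).

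Of 21 tested writers, erasers and readers of DNA methylation, 3 fell, Uhrf1 among them, and 1 rose, also adjusted over the list alone (Fisher's exact test, adjusted p = 0.861). Dnmt1, the maintenance methyltransferase, fell 1.58-fold (48.9 ± 4.68 to 30.9 ± 2.22 FPKM) and the methyl-CpG binding gene Zbtb38 rose 1.61-fold. The chromatin remodeller Hells fell 1.49-fold, and its call was lost without Control 1, Control 3, cKO 1 or cKO 3 (adjusted p = 0.0778 to 0.115).

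Of 38 listed germline genes known to be silenced by promoter methylation, 17 passed the expression filter, of which 16 rose and none fell, and 17 rose adjusted over the list alone. Only 4 of the 17 were above 0 in both groups, so most passed the filter by their level in cKO cells. A fit with a looser filter, added after the data were seen, tested the 34 genes above 0 in any library, and 21 rose and none fell (Fisher's exact test, adjusted p = 4.21e-11). A gene at 0 in every control still entered that fit only by its level in cKO cells, and it could not fall. Rhox5 led. Xlr3b, a member of an X-linked lymphocyte-regulated family, rose from 0.586 ± 0.244 to 6.46 ± 1.84 FPKM, the piRNA-pathway gene Piwil2 from 0.334 ± 0.0645 to 2.57 ± 0.895, and Asz1 was listed at 0 in every control and at 1.82 ± 0.746 in cKO. Members of the Rhox and Xlr families are near-identical copies that can share reads, so which copy rose is uncertain. The authors' deposited test called 9 of the 17, and Piwil2 and Asz1 had too few reads for it. Over the 17 genes Fisher's exact test gave adjusted p = 9.32e-11, and this was the only fixed list still called with an estimated correlation (adjusted p = 0.0222). Without the sex chromosomes 7 members were tested and 6 rose, with adjusted p = 0.000489 by Fisher's exact test. The random lists use only members above 0 in both groups, and this setting also takes out Rhox5 and Xlr3b. Their adjusted p = 0.108 thus rests on too few genes to tell whether the rise depends on the X chromosome. Camera was not run on these 7.

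Imprinted genes, which are expressed from 1 parental copy, went in both directions, with 6 of 25 higher and 6 lower, and 8 and 7 adjusted over the list alone. H19 fell 2.98-fold (3308 ± 223 to 1111 ± 59.7 FPKM) and the neighbouring Igf2 2.62-fold (2545 ± 151 to 971 ± 41.4). Peg10 rose 2.81-fold (90.5 ± 7.13 to 255 ± 4.73) and Gatm from 0.484 ± 0.0779 to 8.82 ± 3.35 FPKM. The number of higher members was 3 without Control 3, cKO 1 or cKO 3. H19 and Igf2 share their intervals with other listed genes. The list was called by Fisher's exact test (adjusted p = 0.00132), with adjusted p = 0.943 at an estimated correlation.

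Of 22 tested interferon-stimulated genes, 21 rose and none fell, with the same count adjusted over the list alone, and Ifit2 was not called. The antiviral oligoadenylate synthetase genes Oas2 and Oas3 rose from 0.0578 ± 0.0502 and 0.0679 ± 0.0675 to 3.14 ± 0.538 and 2.21 ± 1.37 FPKM, and their relative Oasl2 from 0.285 ± 0.119 to 8.52 ± 1.56. The nucleic acid sensor Zbp1 rose from 0.0566 ± 0.0980 to 2.60 ± 1.09 FPKM. The authors' deposited test called 16 of the 22, while Oas2, Oas3 and Zbp1 had too few reads for it. The Oas genes are similar in sequence, so reads can be shared among them. Fisher's exact test gave adjusted p = 3.08e-14 (adjusted p = 0.136 with an estimated correlation).

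Of 16 inflammatory and catabolic genes, 10 rose and 1 fell, also adjusted over the list alone. The acute-phase gene Saa3 rose 15.3-fold (9.72 ± 4.01 to 148 ± 16.3 FPKM), complement C3 7.04-fold and Ptgs2, which encodes cyclooxygenase 2, 4.27-fold. Lif, a cytokine gene, rose from 0.492 ± 0.164 to 1.40 ± 0.346 FPKM, a call lost without Control 1, 2 or 3 or cKO 1 or 2 (adjusted p = 0.0574 to 0.134). Fisher's exact test gave adjusted p = 2.95e-05 (adjusted p = 0.216 with an estimated correlation).

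Markers of other cell types were measured beside these groups. Of 17 skeletal muscle markers 14 passed the filter, and all 14 rose, also adjusted over the list alone. The authors' deposited test called 6 of the 14, but not Mylpf, Myl1, Des or Myh3 (q = 0.0600 to 0.417). Fisher's exact test gave adjusted p = 1.58e-10, with adjusted p = 0.136 at an estimated correlation in camera. Only 10 of the 14 were above 0 in both groups, and a marker silent in controls can pass the filter only by rising. With all genes above 0 in any library, a fit added after the data were seen, Fisher's exact test gave adjusted p = 1.09e-11. In that fit too, a marker at 0 in every control entered only by its level in cKO. Mylpf rose from 0, 0 and 2.15 FPKM in the controls to 64.7 ± 23.6 in cKO, Myl1 to 19.7 ± 4.45, the intermediate filament gene Des from 0.269 ± 0.0972 to 10.7 ± 3.09 and the embryonic myosin Myh3 from at most 0.0535 to 4.91 ± 0.720. Of 8 macrophage and leukocyte markers limma called only Fcer1g, adjusted over all genes or over the list alone, and Lyz2, a macrophage lysozyme, stood at 25.5 ± 19.9 FPKM in control and 9.65 ± 2.28 in cKO (limma adjusted p = 0.361). The authors' deposited test, added after the data were seen, called Lyz2 lower (q = 0.000520) and did not call Fcer1g (q = 0.335). Without Control 3 limma also called Lyz2 lower, and without cKO 1 it also called Cd14 higher (adjusted p = 0.00528 and 0.0212). These values stand beside the cartilage, interferon and inflammatory lists.

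Of 7 adipocyte markers, Plin4 rose 3.91-fold and Pparg fell 1.498-fold, the latter lost without Control 1, Control 3, cKO 2 or cKO 3 (adjusted p = 0.0710 to 0.135). Of 5 neural and Schwann cell markers, Cdh19 rose 6.53-fold and Ncam1 1.67-fold, and S100b, which chondrocytes also express, fell 1.36-fold, a call lost without Control 1, Control 2, cKO 2 or cKO 3 (adjusted p = 0.0677 to 0.117). Counts adjusted over the list alone were the same for both lists. The leukocyte, adipocyte and neural lists were not called by Fisher's exact test (adjusted p = 1, 0.474 and 0.0805), though the neural list was called without cKO 1 (adjusted p = 0.0279). Camera called neither the adipocyte nor the neural list at the preset correlation (adjusted p = 0.844 and 0.114). It called neither with an estimated one (adjusted p = 0.943 and 0.430). The random lists called both (adjusted p = 0.0224 and 0.0195), but not the adipocyte list without Control 1 or cKO 2 (adjusted p = 0.242 and 0.0627). At 5 FPKM or more the random lists also lost it (adjusted p = 0.0866). They did not call the leukocyte list (adjusted p = 0.0616), but did without Control 2, with a median log2 ratio of 1.02, and at 5 FPKM or more, where 2 members were left (adjusted p = 0.0291 and 0.0239). Only 2 endothelial markers were tested. Eng rose 2.80-fold, and Egfl7 was 2.97 ± 1.44 FPKM in control and 2.71 ± 0.774 in cKO. Of 3 osteoclast markers, limma called none adjusted over all genes, 2 had an unadjusted p under 0.05, and 1 was higher and 1 lower adjusted over the list alone. Ctsk stood at 122 ± 9.36 FPKM in control and 103 ± 5.48 in cKO, and Nfatc1 at 10.002 ± 1.202 and 11.005 ± 0.249. No erythroid marker passed the expression filter.

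Hspb1 encodes the small heat shock protein Hsp27 and was chosen in advance from background knowledge that the published study followed it up, which the files used here do not state. It rose 3.53-fold (chromosome 5, 135887919 to 135889563; 14.0 ± 5.01 to 49.3 ± 7.62 FPKM, SD, n = 3; log2 difference 1.80, SE 0.238, limma adjusted p = 0.000914). Its level was higher in all 3 cKO libraries than in any control. The heat shock list was included because of Hspb1, so its direction is not independent evidence. Of its 17 tested genes 4 rose and 1 fell, also adjusted over the list alone. Hspb2 and Cryab, which encode other small heat shock proteins, rose from 0.770 ± 0.278 to 2.67 ± 0.831 FPKM and 1.88-fold, and Hspa5, the main chaperone of the endoplasmic reticulum, fell 1.40-fold (882 ± 40.6 to 630 ± 23.8 FPKM). The list was not called by Fisher's exact test (adjusted p = 0.289), while the random lists and camera at the preset correlation did (adjusted p = 0.00966 and 0.0486; adjusted p = 0.486 with an estimated correlation).

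Of 16 BMP target genes 1 rose and 2 fell, and 2 and 2 adjusted over the list alone (Fisher's exact test, adjusted p = 1). Msx2 rose 1.89-fold, lost without Control 2, Control 3, cKO 1 or cKO 3 (adjusted p = 0.0505 to 0.106). Hey1 fell 1.77-fold, lost without Control 2 or cKO 3 (adjusted p = 0.0544 and 0.0566). Id2 fell 1.19-fold, lost without any single library (adjusted p = 0.0617 to 0.167). Of 12 hedgehog, PTHrP and FGF genes only Fgfr3, a receptor that restrains chondrocyte proliferation, fell, 1.75-fold (246 ± 49.1 to 140 ± 8.50 FPKM), also adjusted over the list alone, and Fgfr2 stood at 81.3 ± 7.35 and 83.1 ± 8.48 (list adjusted p = 0.823).

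Of 12 Wnt pathway genes, Sfrp2, Frzb and Lef1 fell (6.26-, 2.75- and 2.65-fold) and 2 rose, of which Dkk3 rose 2.44-fold (45.4 ± 7.63 to 111 ± 4.87 FPKM). The list median was 0.32, opposite in sign to most of its called members, and 4 rose and 3 fell adjusted over the list alone. Fisher's exact test did not call it (adjusted p = 0.0813), while the random lists did (adjusted p = 0.0352; camera adjusted p = 0.943 with an estimated correlation). The random-list call was lost without Control 2, Control 3, cKO 1 or cKO 2 (adjusted p = 0.0685, 0.343, 0.295 and 0.0732) and with all genes above 0 in any library (adjusted p = 0.187). The list was called by Fisher's exact test without Control 2, cKO 1 or cKO 3 (adjusted p = 0.0237, 0.00350 and 0.0111), and with all libraries at a threshold of 0.01, a log2 difference of at least 1 or at least 5 FPKM (adjusted p = 0.0293, 0.00364 and 0.0253). It was also called with the genes of the authors' deposited test (adjusted p = 0.00472). Of 20 glycolysis and hypoxia genes 1 rose and 5 fell, and 1 and 7 adjusted over the list alone (Fisher's exact test, adjusted p = 0.224; random lists, adjusted p = 0.0369; camera, adjusted p = 0.0179 at the preset correlation and adjusted p = 0.574 with an estimated correlation). The random-list call was lost without Control 3, cKO 1 or the sex chromosomes, and with a pseudocount of 1 (adjusted p = 0.343, 0.0997, 0.0665 and 0.0534). Pgk1 fell 1.46-fold. Pgam1 fell 1.27-fold, lost without cKO 2 or cKO 3 (adjusted p = 0.0568 and 0.0514). Pdk1 fell 1.27-fold, lost without any single library (adjusted p = 0.0646 to 0.148). Pfkp rose 1.30-fold, a call that held only without Control 3 (adjusted p = 0.0727 to 0.124 without the others).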

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

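The signal below lies in genes too low for the main test, and it was looked for after the data were seen. Among the 11440 genes under the expression filter, 145 were listed at 0 in all 3 control libraries and above 0 in all 3 cKO libraries, against 37 with the reverse. With named single-symbol genes alone the counts were 122 and 33. The 4 highest with a single symbol were Atp2a1, a calcium pump of skeletal muscle, at a cKO mean of 1.42 FPKM, Bglap3 at 1.34, Cacng1 at 1.08 and Sectm1a at 1.08. Dppa4, a gene of pluripotent cells, stood at 0.828 FPKM, Magea10 at 0.813 and the meiotic gene Stra8 at 0.616. These levels rest on few reads each.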

How the results depend on the processing

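The authors' deposited test, the Y-linked covariate, the removal of the sex chromosomes and the test of all genes above 0 in any library were chosen after seeing the data. The number of called genes (2116, of which 1168 higher and 948 lower) moved by over 1.5 times with a threshold of 0.01 (1024, 647 and 377) and with a log2 difference of at least 1 (506, 431 and 75), both stricter by construction. Leaving out 1 library gave 1277 to 1994 called, 775 to 1089 higher and 502 to 930 lower genes, with 1091 of the called genes kept each time. The lowest numbers came without cKO 3 (1277, 775 and 502), and the lower genes also numbered 598 without cKO 1 and 629 without cKO 2, with fewer samples in each fit. No called gene shared with an alternative changed sign. The authors' test called 2225 genes, 1605 of them shared. The covariate left 1654 and removing the sex chromosomes 1993, and testing all 16187 genes above 0 in any library gave 1941 (1153 higher, 788 lower).

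Uhrf1 was lower under every alternative run, and its log2 ratio of means of -3.16 became -2.81 with a pseudocount of 1, which shrinks ratios by construction. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.169, 0.0258 and -0.0443. With replicate as a block 2097 genes were called (1151 higher, 946 lower), 12 lists in place of 10 were called by Fisher's test, with the osteoblast list (adjusted p = 0.0340) and the adipocyte list (5 of 7 members in place of 2, adjusted p = 0.00542) added, and Uhrf1 stayed at -2.80. List calls by Fisher's test ranged from 9 to 12 over all alternatives, with the osteoblast and Wnt lists added by the authors' test (adjusted p = 0.00503 and 0.00472). The median log2 ratio of adipocyte markers, -0.42, reversed to 0.30 with at least 5 FPKM in the higher group, leaving 4 of 7 members. That of imprinted genes, 0.09, reversed to -0.0544 with all genes above 0 in any library, which takes in 8 more members by construction. No named gene reversed, while over all named genes and settings 155 comparisons were weaker and 4 stronger, against 1888 unchanged. The count test on recovered reads was not run. Other splits of the 6 libraries, 3 against 3, make 10 splits with the real one, too few for a share under 0.05: 1 of the 10, the real split, called 2116 genes, and the highest other split called 4. Unknown absolute depth leaves the precision of genes near 1 FPKM to the replicate spread.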

Other observations

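The limma test, the fixed lists with their random lists, and upper-quartile scaling were planned. The other lists, tests and comparisons in this part, including the use of that scaling on an explanation, were chosen after the results were seen. Genes of antigen presentation by class I molecules rose in cKO cells: all 15 tested members were called, also adjusted over the list alone (limma; Fisher's exact test, adjusted p = 2.13e-11; adjusted p = 0.0633 with an estimated correlation). B2m, the common light chain, rose from 392 ± 38.1 to 1108 ± 127 FPKM, H2-K1 from 41.4 ± 10.2 to 176 ± 27.2, and the immunoproteasome subunit Psmb8 from 1.32 ± 0.437 to 15.3 ± 4.21. Of 11 smooth muscle and contractile genes 8 rose, also adjusted over the list alone (Fisher's exact test, adjusted p = 0.000194; adjusted p = 0.140 with an estimated correlation). Actg2, the smooth muscle gamma-actin, rose from 4.37 ± 1.22 to 49.7 ± 10.6 FPKM and Acta2 from 210.0 ± 46.2 to 354 ± 58.7, while Tagln was 90.8 ± 30.0 and 98.1 ± 10.2 (adjusted p = 0.637). Of 19 chaperone and secretory genes of the endoplasmic reticulum 8 fell, and 10 adjusted over the list alone, among them Hsp90b1, from 781 ± 59.2 to 617 ± 23.6 FPKM (list adjusted p = 0.0154; adjusted p = 0.140 with an estimated correlation). Of 15 cholesterol synthesis genes limma called none, also adjusted over the list alone, 4 had an unadjusted p under 0.05, and the authors' deposited table called 4 (Fisher's exact test, adjusted p = 0.0895).

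In cKO 1, which carries Y-linked transcripts, Xist stood at 5.58 FPKM, against 0.0526 and 0.112 in Control 1 and Control 3, which also carry them. Uba1y, a Y-linked gene, stood at 11.5 FPKM in cKO 1 and was listed at 0 in the other 5 libraries.

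Skeletal muscle genes were higher in cKO cells, with a median log2 difference of 2.49. A lower share of chondrocytes would raise other cell types present in the cultures, and 25 markers of 5 other cell types had a median of 0.13. This median cannot decide the question. Only 2 endothelial and 3 osteoclast markers passed the filter, chondrocytes also express S100b, and a cell type that is absent cannot rise. Outside the 25 markers, 4 of 10 osteoblast and 8 of 11 contractile genes rose and none fell. Skeletal muscle cells in the cKO cultures stay a candidate explanation. Outside the 14 tested markers, 32 muscle genes were above 0 in any library. Of these, 78.1% lay above 0 in all 3 cKO libraries with a higher mean than in control. The share was 43.2% of the other genes above 0 in any library (Fisher's exact test, p = 9.55e-05). Ckm, Ttn and Myh8, among the 32, are members of the fixed list that did not pass the filter. Muscle genes at 0 in every control could not come out lower, and the other genes were not matched on level. This test therefore cannot decide the question. Mb, the myoglobin gene, and Ckm, the muscle creatine kinase gene, were listed at 0 in every control and stood at 6.88 and 0.361 FPKM in cKO. Tnnc1 stood at 2.47 FPKM in control and 15.3 in cKO, while Pax7, a gene of muscle precursors, was listed at 0 in every library. Activation of muscle genes within chondrocytes would give the same rise in this list and stays open, as does whatever differs between the label prefixes.

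Interferon-stimulated genes were higher in cKO, with a median log2 difference of 1.97. A larger share of leukocytes was taken to raise leukocyte markers at least as much. All 8 tested markers had a median log2 ratio of 0.70 against 3.00 for the interferon genes (exact Wilcoxon rank-sum test, p = 0.00302). Among random lists the markers lay at the 97.8 percentile, or 99.0 without Control 2, where their median was 1.02. Control levels differed, with Oas2 at 0.0578 FPKM and Lyz2 at 25.5, and a control level near 0 enlarges a log2 ratio. Genes of a list are also not independent, so this p-value does not measure the share of leukocytes. Fcer1g alone exceeded the interferon median (0.234 to 15.8 FPKM), and the other 7 markers lay under it. Fcer1g and a response of leukocytes already present stay open. After upper-quartile scaling 100% of the called members stayed called. That scaling multiplied cKO libraries by 1.01 to 1.03 and controls by 0.96 to 0.99, so it could hardly undo a rise. It therefore cannot test scaling as an explanation, though the factors themselves were small beside the median log2 ratio of 3.00. A difference between the label prefixes cannot be told apart from genotype, because 0 prefixes hold both groups. A response to the loss of Uhrf1 is a hypothesis that may be followed up with repeat-derived transcripts, which were not analysed here.

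X-linked genes were called higher more often than autosomal ones (14.1% of 434 against 9.65%; Fisher's exact test, p = 0.00387). Of the 61 X-linked genes called higher, 31 were listed at 0 in every control, against 80 of all 1168 genes called higher. Such a gene passed the expression filter only by its level in cKO cells and could not fall. Part of the X-linked share thus rests on genes that could not have been called lower. Unequal numbers of libraries with Y-linked transcripts did not account for the excess. With that covariate 12.4% of all tested X-linked genes were called higher against 7.85% of autosomal ones (Fisher's exact test, p = 0.00112). Of the 61 genes called without the covariate, 52 stayed called. Reads shared within multi-copy families stay a candidate source of the excess. Without Rhox, Xlr and Mage symbols and unnamed genes, 7.94% of 378 X-linked genes were called higher, against 9.67% of autosomal genes (Fisher's exact test, p = 0.287). Whether each copy is transcribed or a few copies lend reads to the rest may be settled only with reads.

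Limma alone called 511 genes, of which 288 had too few reads for the authors' test, and the authors alone called 619 within the expression filter. Among the 288 were Piwil2, Asz1, Oas2, Oas3, Zbp1, Hspb2, Lif, Pmaip1 and Gng13. For genes called higher that both tested, the authors' deposited table and limma parted most often, as a share, where 1 or 2 controls were at 0. Of the genes limma called higher and the authors tested, the authors called 799 of 876 with no control library at 0 and 30 of 32 with all 3 at 0, but 2 of 12 with 1 at 0 and 0 of 15 with 2 at 0. Rhox5 is among the last, with a deposited q-value of 0.335 in the authors' deposited table beside a limma adjusted p of 7.99e-08.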
